A study of Arabidopsis thaliana with 24 samples.

How the data were processed

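RNA was measured by sequencing in shoots of Arabidopsis thaliana seedlings of 4 genotypes. These were the wild type Col-0, the catalase mutant cat2, the SHORT-ROOT mutant shr and the double mutant cat2shr. Each genotype was sampled at 0 h and at 24 h of photorespiratory stress, with 3 replicates per group, which gave 8 groups and 24 libraries. Per the labels, plants grew for 21 days on agar with 1% sucrose at 21 °C under 16 h light of 100 µmol per square metre per second and 8 h dark. Gas exchange was then restricted by sealing the plates with Parafilm, and light became continuous. The RNA was extracted with TRIzol and an RNeasy kit, and libraries were made with a TruSeq Stranded mRNA kit.

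The values used are the deposited gene counts, which the authors left as raw whole numbers for 33602 loci. Per the submitters' processing notes, these came from Trim Galore 0.3.3, TopHat2 2.1.0 and featureCounts of Subread 1.4.6 on genome build TAIR10. Their order, parameters, strand setting and annotation release are not given in the sources used here. The table held 6798 loci with 0 counts in every library. Loci were paired with gene symbols through a RefSeq annotation by locus tag, which matched 32835 of 33602 loci. Of the 439 genes in the lists, 415 had the same symbol in that annotation and 24 did not, so the locus is given with each symbol at its first mention. No coordinates are reported.

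Total counts per library ranged from 26.43 to 40.11 M counts. Values in CPM, counts per M counts of a library, used library sizes scaled by trimmed mean of M-values (TMM) factors. Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left 20347 genes. A quasi-likelihood model (glmQLFit with robust estimation) with 1 mean per group was fitted to all 24 libraries, with a common dispersion of 0.0195. It was tested by glmQLFTest for 15 contrasts. These were the stress response in each of the 4 genotypes, 3 genotype differences at each time, 4 differences between stress responses and 1 three-way interaction. The genotype differences were cat2 against Col-0, shr against Col-0 and cat2shr against cat2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Standard errors (SE) were the log2 fold change divided by the square root of F. A value after ± is the SE beside a log2 change and the SD over 3 libraries beside CPM. The p-values measure only the spread between these samples, and the plants behind each library are not described further.

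Before the data were examined, 23 gene lists were fixed from general knowledge, with 6 reference genes as a check. They cover oxidative stress markers, tau and phi glutathione S-transferases, heat shock proteins and factors, and salicylic acid and pathogen defence. They also cover jasmonate synthesis and signalling, abscisic acid and dehydration, the low-oxygen response, photorespiration, photosynthesis and antioxidant enzymes. Further lists hold anthocyanin and flavonoid synthesis, sugar starvation markers, starch, sucrose and sugar transport, glucosinolate synthesis, phosphate starvation, iron deficiency, the cell cycle and the SHORT-ROOT regulon. The last lists hold senescence and cell death, the circadian clock, and root, floral organ and vascular markers. Each list was compared with all other genes by camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. Its p was adjusted by Benjamini-Hochberg over the 23 lists of a contrast. Camera was also run with a correlation estimated from the data and on ranks. Members called by edgeR were counted over all genes tested and again adjusted over the list alone, and the second pair of counts is given where it differed. Members are those of a list that passed the filter.

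The genes named were set by a rule fixed at the same time. It took CAT2, SHR, up to 5 genes with the largest rise and 5 with the largest fall in each contrast, and the members of each list with the smallest adjusted p. Genes with the largest changes had to be called, to have a mean of at least 5 CPM over all libraries and, where 2 groups were compared, no overlap between the libraries of the groups. Genes with 3 counts or fewer in a whole group are given as CPM, not as a fold. Exceptions chosen after their values were seen are named as such in the closing part.

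The alternatives were library scaling by relative log expression (RLE) or by library size only, no filter on low counts, and a filter of 5 CPM in 3 libraries. DESeq2 1.42.0, a replicate block, a fit on only the groups compared, and the omission of each library in turn were the others. After the libraries were seen, 1 alternative was added, which left out shr replicate 1 and cat2shr replicate 1 at 0 h. Other splits of the same libraries were fitted to compare counts of called genes. The procedure was tested on simulated data of this design with 112 of 20040 genes changed 2-fold and 88 4-fold, not under widespread change. For the cat2 response it recovered 80.4% and 92%, with 4 of 175 calls false. For the three-way interaction it recovered 39.3% and 77.3%. For an unchanged Col-0 response it made 0 calls.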

Results

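Gene counts were measured in shoots of 3-week-old seedlings of Col-0, cat2, shr and cat2shr at 0 h and 24 h of photorespiratory stress, with n = 3 libraries in each of the 8 groups. The title of the series concerns how the lack of SHORT-ROOT changes the cell death phenotype of the catalase2 mutant under conditions that promote photorespiration. Mean totals at 0 h were 30.01 M counts in Col-0, 28.86 in cat2, 34.59 in shr and 28.16 in cat2shr. At 24 h they were 26.56 M in Col-0, 31.9 in cat2, 28.38 in shr and 38.46 in cat2shr. Totals per library ran from 26.43 M to 40.11 M. The 10 most abundant genes held between 3.88% and 9.36% of the counts of a library.

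CAT2 (AT4G35090), the main leaf catalase that removes photorespiratory hydrogen peroxide, measured 374 ± 150 CPM (SD, n = 3) in Col-0 at 0 h and 890 ± 221 CPM at 24 h. In cat2 it measured 17.5 ± 4.00 CPM and 28.1 ± 3.19 CPM. It was lower in cat2 than in Col-0 at 0 h (log2 -4.42, SE 0.34, adjusted p = 1.56e-07) and at 24 h (log2 -4.99, SE 0.34, adjusted p = 8.37e-10). SHR (AT4G37650), a transcription factor of the endodermis and bundle sheath, measured 9.96 ± 0.740 CPM in Col-0 and 1.04 ± 0.0244 CPM in shr at 0 h. It was lower in shr than in Col-0 at 0 h (log2 -3.25, SE 0.14, adjusted p = 3.99e-12) and at 24 h (log2 -3.40, SE 0.15, adjusted p = 4.33e-12). In cat2shr it was lower than in cat2 at 0 h (log2 -3.73, SE 0.15, adjusted p = 4.95e-12) and at 24 h (log2 -3.50, SE 0.15, adjusted p = 1.82e-12). CAT2 was also lower in shr than in Col-0, at 0 h (log2 -0.84, SE 0.29, adjusted p = 0.0252) and at 24 h (log2 -1.23, SE 0.29, adjusted p = 0.00184). SHR was lower in cat2 than in Col-0 at 0 h (log2 -0.35, SE 0.12, adjusted p = 0.0411) and at 24 h (log2 -0.53, SE 0.12, adjusted p = 0.000985). At 0 h the difference of CAT2 in shr was not called without Col-0 replicate 3 (log2 -0.42, SE 0.28, adjusted p = 0.251) or shr replicate 1 (log2 -0.53, SE 0.29, adjusted p = 0.143). That of SHR in cat2 at 0 h was called in 1 of 6 fits with 1 library left out, without cat2 replicate 1 (adjusted p = 0.0496), and had adjusted p from 0.0998 to 0.249 in the others.

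**Figure D1:**
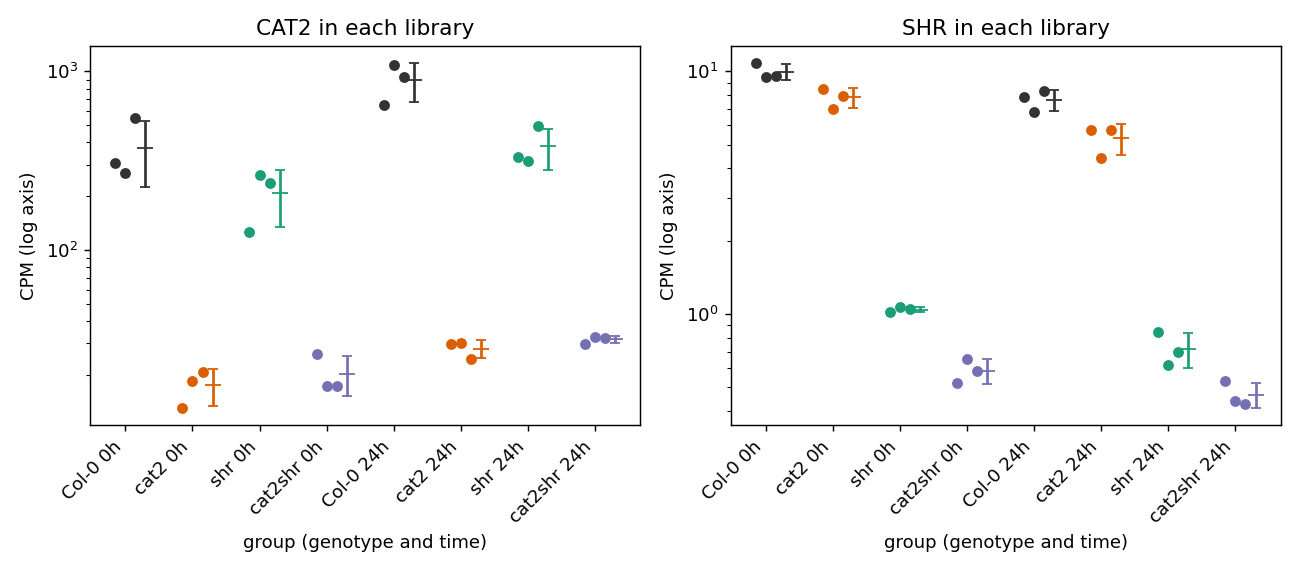
CPM of CAT2 and SHR on log axes in each library (points) of the 8 groups, with the group mean and SD (bars) beside them. CAT2 stayed at or below 32.5 CPM in cat2 and cat2shr, and SHR at or below 1.07 CPM in shr and cat2shr.

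Across all genes, the first principal component held 49.3% of the variance, the second 20% and the third 9.8%. On the second component the groups with an intact SHR gene had means from -57.8 to -34.5, and the shr and cat2shr groups from 43.2 to 47.6. On the first component Col-0 at 0 h had the lowest group mean, -106.1 ± 2.9 (SD), and cat2 at 24 h the highest, 131.3 ± 20.5. The shr groups moved from -46.1 ± 26.7 at 0 h to -4.3 ± 5.9 at 24 h, and the cat2shr groups from -28.9 ± 12.5 to 86.5 ± 8.7. At 0 h, shr replicate 1 stood apart from the other shr libraries, with 1172 genes more than 2-fold from their mean. Its oxidative stress markers had a median log2 distance of -1.53, its heat shock genes -1.40, its jasmonate genes -0.95 and its sugar starvation markers -0.93, against 0.09 for photosynthesis genes. The median absolute log2 distance from the other libraries of a group was highest in cat2 replicate 3 at 24 h, 0.195. It was 0.184 in cat2shr replicate 1 at 0 h, 0.178 in cat2 replicate 2 at 24 h, 0.17 in cat2shr replicate 3 at 0 h and 0.159 in shr replicate 1 at 0 h.

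**Figure D2:**
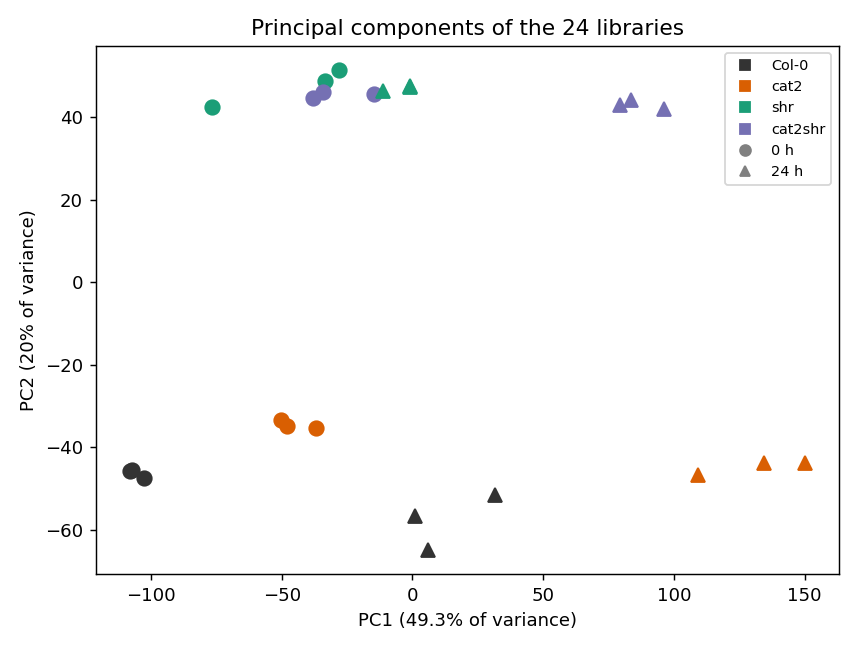
Positions of the 24 libraries on the first 2 principal components of log2 CPM (axes in component units, colour for genotype, circles for 0 h and triangles for 24 h). The second component separated libraries with low SHR (upper) from the rest (lower).

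Among the reference genes, PP2AA3 (AT1G13320) was called in 1 of the 15 contrasts, the stress response in shr (log2 0.17, SE 0.06, adjusted p = 0.0338). UBQ10 (AT4G05320) rose under stress in Col-0 (log2 1.21, SE 0.19, adjusted p = 2.05e-05) and in cat2 (log2 1.68, SE 0.19, adjusted p = 1.6e-07).

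The stress response in Col-0 asked what changed from 0 h to 24 h in wild-type shoots. With no untreated group at 24 h, sealing, continuous light and elapsed time cannot be separated in any genotype. Among cell cycle genes, 23 of 25 members fell and 0 rose (camera adjusted p = 2.78e-12, adjusted p = 0.271 with an estimated correlation). MCM5 (AT2G07690, log2 -1.97, SE 0.12, adjusted p = 1.32e-10) and MCM2 (AT1G44900, log2 -2.03, SE 0.13, adjusted p = 4.55e-10), which license DNA replication, fell together. Of the glucosinolate synthesis genes, 17 of 19 members fell and 1 rose (camera adjusted p = 2.42e-07, adjusted p = 0.271 with an estimated correlation). These included MYB29 (AT5G07690, log2 -3.39, SE 0.29, adjusted p = 1.39e-08), a regulator of aliphatic glucosinolates, and CYP83A1 (AT4G13770, log2 -3.54, SE 0.30, adjusted p = 2.55e-08). In the photosynthesis list 22 of 29 members fell and 1 rose (camera adjusted p = 2.42e-07, adjusted p = 0.804 with an estimated correlation). These included the antenna genes LHCB6 (AT1G15820, log2 -1.76 ± 0.14) and LHCB5 (AT4G10340, log2 -1.22 ± 0.13). In the iron deficiency list 11 of 12 members fell and 0 rose (camera adjusted p = 0.00244, adjusted p = 0.804 with an estimated correlation). Among them was the transcription factor BHLH100 (AT2G41240, log2 -4.97, SE 0.58, adjusted p = 9.66e-07). Of the sugar starvation markers, 10 of 10 members rose and 0 fell (camera adjusted p = 3.14e-06, adjusted p = 0.369 with an estimated correlation). They included AKINBETA1 (AT5G21170, log2 2.44, SE 0.16, adjusted p = 5.15e-10) and DIN10 (AT5G20250, log2 3.88, SE 0.26, adjusted p = 1.13e-09).

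Oxidative stress markers and glutathione S-transferases also rose in Col-0, while antioxidant enzymes went both ways, as 8 of 26 members rose and 8 fell (camera adjusted p = 0.901). Of the oxidative stress markers, 21 of 28 members rose and 0 fell (camera adjusted p = 0.000689, adjusted p = 0.804 with an estimated correlation). Among them were ERF5 (AT5G47230, log2 2.42, SE 0.27, adjusted p = 2.42e-07) and OPR1 (AT1G76680, log2 3.98, SE 0.47, adjusted p = 1.18e-06). Of the glutathione S-transferases, 16 of 24 members rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.804 with an estimated correlation), with GSTF2 (AT4G02520, log2 5.07 ± 0.38) and GSTF6 (AT1G02930, log2 5.39 ± 0.40) up and GSTU20 (AT1G78370, log2 -2.97 ± 0.26) down. The largest rise in Col-0 was in AT4G25580 (0.0237 ± 0.0208 CPM in Col-0 at 0 h and 22.3 ± 11.7 CPM in Col-0 at 24 h). GLYI7 (AT1G80160, log2 8.12 ± 1.22), of the glyoxalase I family, and GAT1_2.1 (AT1G15040, log2 7.98 ± 0.59), a glutamine amidotransferase, ranked at 4 and 5. Falls were largest in AOP2 (AT4G03060, log2 -5.94 ± 0.47), of glucosinolate side chains, and AT5G03350 (log2 -5.16 ± 0.55). Senescence regulators NAC092 (AT5G39610, log2 4.45, SE 0.40, adjusted p = 5.19e-08) and NAP (AT1G69490, log2 3.94, SE 0.39, adjusted p = 1.59e-07) rose, though the senescence list as a whole was not called, as 10 of 18 members rose and 6 fell (camera adjusted p = 0.23). Altogether 12064 of 20347 genes were called, 6046 higher and 6018 lower, of which 1674 and 2194 changed at least 2-fold.

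The stress response in cat2 asked what changed from 0 h to 24 h in shoots of the catalase mutant, without a comparison with Col-0. Heat shock genes stood out, as 21 of 22 members rose and 0 fell (camera adjusted p = 4.13e-07, adjusted p = 0.509 with an estimated correlation). The immunophilin ROF2 (AT5G48570, log2 2.86, SE 0.21, adjusted p = 3.38e-10) and the regulator DREB2A (AT5G05410, log2 3.99, SE 0.29, adjusted p = 6.54e-10) rose. Among low-oxygen genes, 11 of 13 members rose and 2 fell (camera adjusted p = 0.00245, adjusted p = 0.509 with an estimated correlation). These included the fermentation genes PDC1 (AT4G33070, log2 4.25, SE 0.41, adjusted p = 2.81e-08) and ADH1 (AT1G77120, log2 3.03, SE 0.39, adjusted p = 1.31e-06). Among jasmonate genes, 18 of 24 members fell and 2 rose (camera adjusted p = 0.00544, adjusted p = 0.692 with an estimated correlation). The synthesis genes LOX2 (AT3G45140, log2 -4.04, SE 0.35, adjusted p = 6.09e-09) and AOS (AT5G42650, log2 -3.30, SE 0.41, adjusted p = 1e-06) fell, while the defensin PDF1.2 (AT5G44420, log2 5.46, SE 0.58, adjusted p = 1.24e-07) rose. In the photorespiration list 14 of 20 members fell and 4 rose (camera adjusted p = 0.011, adjusted p = 0.692 with an estimated correlation). They included the glycine decarboxylase subunit GDCH (AT2G35370, log2 -1.73 ± 0.13) and the glutamine synthetase GS2 (AT5G35630, log2 -1.08 ± 0.08). In the photosynthesis list 28 of 29 members fell and 0 rose (camera adjusted p = 3.13e-09, adjusted p = 0.509 with an estimated correlation).

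In cat2 the oxidative stress markers also rose, as 26 of 28 members rose and 0 fell (camera adjusted p = 2.41e-05, adjusted p = 0.559 with an estimated correlation). UPOX (AT2G21640, log2 3.31, SE 0.30, adjusted p = 1.46e-08), a mitochondrial marker of oxidative stress, and SRO5 (AT5G62520, log2 4.54, SE 0.47, adjusted p = 7.81e-08) were among them. In the cell cycle list 22 of 25 members fell and 3 rose (camera adjusted p = 2.08e-06, adjusted p = 0.509 with an estimated correlation). Among them were MCM7 (AT4G02060, log2 -2.59 ± 0.13) and MCM5 (log2 -2.14 ± 0.12). Of the floral organ markers, 4 of 7 members rose and 0 fell (camera adjusted p = 0.345). These included PI (AT5G20240, log2 2.13, SE 0.48, adjusted p = 0.000492), SEP2 (AT3G02310, log2 2.82, SE 0.76, adjusted p = 0.00234) and AP1 (AT1G69120, log2 3.17, SE 0.88, adjusted p = 0.00298). The largest rises were in BGLU30 (AT3G60140, log2 11.28, SE 1.90, adjusted p = 3.3e-05), a beta-glucosidase gene induced by darkness, GLYI7 (log2 9.48, SE 1.15, adjusted p = 6.29e-07) and THA1 (AT1G08630, log2 9.25, SE 0.41, adjusted p = 1.88e-12), a threonine aldolase. The largest falls were in TPS03 (AT4G16740, log2 -6.79, SE 0.73, adjusted p = 1.32e-07), a terpene synthase, AT1G31690 (log2 -6.20, SE 0.25, adjusted p = 3.95e-13) and IMS2 (AT5G23020, log2 -6.09, SE 0.37, adjusted p = 2.75e-11), of glucosinolate chain elongation. In total 15265 genes were called, 7876 higher and 7389 lower, and 3371 and 3594 changed at least 2-fold. Scaled by library size only, the median log2 of all genes was -0.077, against 0.027.

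The stress response in shr asked what changed from 0 h to 24 h in shoots without SHR. Antenna genes fell, and in the photosynthesis list 26 of 29 members fell and 0 rose (27 and 0 adjusted over the list alone, camera adjusted p = 6.43e-15, adjusted p = 0.644 with an estimated correlation). LHB1B1 (AT2G34430, log2 -2.48, SE 0.19, adjusted p = 2.94e-08) and LHCA1 (AT3G54890, log2 -1.36, SE 0.12, adjusted p = 1.56e-07) were among them. Of the jasmonate genes, 19 of 24 members fell and 2 rose (camera adjusted p = 0.00461, adjusted p = 0.887 with an estimated correlation), with the storage protein gene VSP2 (AT5G24770, log2 -3.55, SE 0.45, adjusted p = 1.01e-05) down and the defensin PDF1.2 (log2 2.84, SE 0.48, adjusted p = 0.000162) up. In the anthocyanin list 13 of 20 members fell and 4 rose (14 and 4 adjusted over the list alone, camera adjusted p = 0.0368, adjusted p = 0.887 with an estimated correlation). Chalcone synthase CHS (AT5G13930, log2 -2.25, SE 0.26, adjusted p = 2.4e-06) and the regulator MYB75 (AT1G56650, log2 -4.30, SE 0.56, adjusted p = 9.07e-06) fell. In the list of starch, sucrose and sugar transport 8 of 18 members fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.644 with an estimated correlation). They included SWEET12 (AT5G23660, log2 -0.79 ± 0.11), a sucrose exporter, and BAM3 (AT4G17090, log2 -0.60 ± 0.11), a beta-amylase. Of the sugar starvation markers 8 of 10 members rose and 0 fell (camera adjusted p = 0.000153, adjusted p = 0.644 with an estimated correlation). Replicate 1 of shr at 0 h lay below the other shr libraries in the jasmonate list and these markers, by a median log2 of -0.95 and -0.93.

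Of the cell cycle genes in shr, 11 of 25 members fell and 0 rose (camera adjusted p = 0.00326, adjusted p = 0.887 with an estimated correlation). They included CYCD3;1 (AT4G34160, log2 -0.82, SE 0.15, adjusted p = 0.000215) and CYCA2;4 (AT1G80370, log2 -0.89, SE 0.18, adjusted p = 0.000547). Of the oxidative stress markers, 6 of 28 members fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.854), so the list was not called. Replicate 1 at 0 h lay below the other shr libraries in this list by a median log2 of -1.53. The largest rises were in AT3G62950 (log2 4.51, SE 0.73, adjusted p = 9.39e-05), UPB1 (AT2G47270, log2 4.33, SE 0.17, adjusted p = 1.93e-12), a transcription factor of peroxidase genes, and AT3G20395 (log2 4.23, SE 0.30, adjusted p = 1.56e-08). Falls were largest in TPS03 (log2 -4.17, SE 0.62, adjusted p = 5.16e-05), MBP1 (AT1G52040, log2 -3.87, SE 0.55, adjusted p = 3.28e-05), a myrosinase-binding protein, and VSP2 (log2 -3.55, SE 0.45, adjusted p = 1.01e-05). Altogether 8404 genes were called, 4152 higher and 4252 lower, and 497 and 1156 changed at least 2-fold. Scaled by library size only, 65.2% of the called genes were higher, against 49.4%.

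The stress response in cat2shr asked what changed from 0 h to 24 h in the double mutant. Oxidative stress markers rose, as 22 of 28 members rose and 0 fell (camera adjusted p = 0.000148, adjusted p = 0.575 with an estimated correlation). WRKY6 (AT1G62300, log2 2.49, SE 0.33, adjusted p = 3.78e-06) and the glucosyltransferase UGT73B5 (AT2G15480, log2 3.17, SE 0.46, adjusted p = 9.59e-06) were among them. In the iron deficiency list 12 of 12 members fell and 0 rose (camera adjusted p = 0.000273, adjusted p = 0.467 with an estimated correlation). Among them were IMA3 (AT2G30766, log2 -1.95, SE 0.25, adjusted p = 1.87e-06), a peptide that signals iron deficiency, and FRO3 (AT1G23020, log2 -1.27, SE 0.17, adjusted p = 2.94e-06), a ferric reductase. Of the low-oxygen genes, 10 of 13 members rose and 1 fell (camera adjusted p = 0.0155, adjusted p = 0.467 with an estimated correlation). Among them were SUS1 (AT5G20830, log2 2.50, SE 0.29, adjusted p = 6.67e-07), a sucrose synthase, and ADH1 (log2 3.26, SE 0.39, adjusted p = 1.15e-06). Heat shock genes rose in part, as 10 of 22 members rose and 1 fell (camera adjusted p = 0.0338, adjusted p = 0.732 with an estimated correlation). These included HSFB2A (AT5G62020, log2 1.68 ± 0.20) and HSFA4A (AT4G18880, log2 1.26 ± 0.18). Among cell cycle genes, 21 of 25 members fell and 0 rose (camera adjusted p = 6.07e-06, adjusted p = 0.467 with an estimated correlation). Of the salicylic acid genes, 9 of 25 members fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.263), and the defence regulators SAG101 (AT5G14930, log2 -0.85, SE 0.11, adjusted p = 1.42e-06) and EDS1 (AT3G48090, log2 -0.80, SE 0.16, adjusted p = 0.000176) fell.

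The largest rises in cat2shr were in AT4G25580 (0.035 ± 0.0363 CPM in cat2shr at 0 h and 10.5 ± 4.25 CPM in cat2shr at 24 h), BGLU30 (log2 5.98, SE 1.31, adjusted p = 0.000655) and AT5G22140 (log2 5.61, SE 0.33, adjusted p = 7.33e-10). The largest falls were in AOP2 (log2 -4.37, SE 0.51, adjusted p = 5.8e-07), AT5G03120 (log2 -4.18, SE 0.34, adjusted p = 9.1e-09) and SWEET13 (AT5G50800, log2 -3.85, SE 0.40, adjusted p = 1.59e-07), a sucrose exporter. In total 13103 genes were called, 6654 higher and 6449 lower, and 1957 and 2256 changed at least 2-fold. Under library size scaling alone, 40% were higher, against 50.8%, and the median log2 of all genes was -0.132, against 0.001.

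Stress responses were compared between genotypes gene by gene. Of the genes called in cat2 and in cat2shr, 10975 had the same sign and 367 the opposite sign. Among the 6965 genes with at least a 2-fold response in cat2, the median size was 1.64 in cat2 and 1.01 in cat2shr. Among the 4213 chosen in cat2shr, it was 1.72 in cat2 and 1.5 in cat2shr. For Col-0 and shr, 6008 genes had the same sign and 265 the opposite sign. Among the 3868 genes chosen in Col-0 the medians were 1.63 in Col-0 and 0.68 in shr, and among the 1653 chosen in shr they were 1.43 and 1.44.

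**Figure D3:**
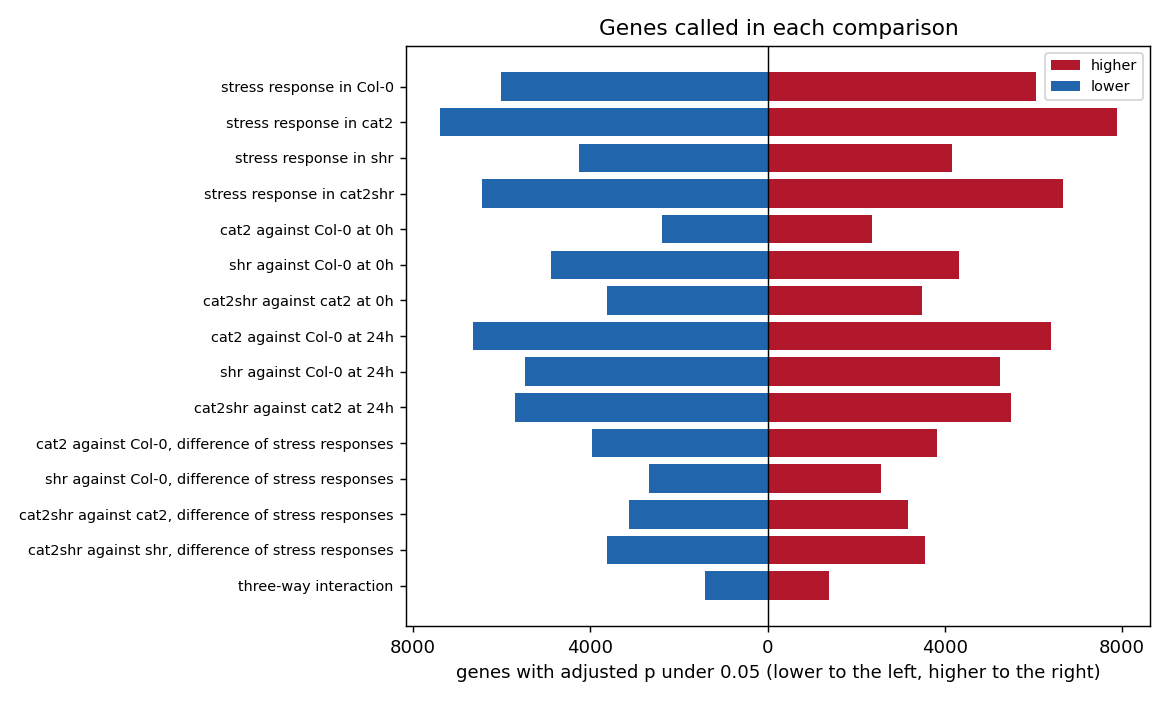
Number of genes called at an adjusted p under 0.05 in each contrast, lower to the left and higher to the right (bars). The stress response in cat2 had the most called genes, 15265, and the three-way interaction the fewest, 2794.

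The comparison of cat2 with Col-0 at 0 h asked what loss of the catalase changes before stress. Jasmonate, oxidative stress, low-oxygen and part of the heat shock genes were higher in cat2, and dehydration genes were lower. In the jasmonate list 19 of 24 members were higher and 0 were lower (21 and 0 adjusted over the list alone, camera adjusted p = 3.77e-13, adjusted p = 0.178 with an estimated correlation). They included the repressor JAZ2 (AT1G74950, log2 1.95, SE 0.29, adjusted p = 0.000148) and the synthesis genes AOC2 (AT3G25770, log2 1.59, SE 0.29, adjusted p = 0.00084) and OPR3 (AT2G06050, log2 2.52, SE 0.46, adjusted p = 0.000877). Of the oxidative stress markers, 24 of 28 members were higher and 0 were lower (26 and 0 adjusted over the list alone, camera adjusted p = 1.23e-11, adjusted p = 0.204 with an estimated correlation). These included OPR1 (log2 3.75, SE 0.47, adjusted p = 3.02e-05) and WRKY25 (AT2G30250, log2 1.95, SE 0.30, adjusted p = 0.000182). In the low-oxygen list 9 of 13 members were higher and 0 were lower (camera adjusted p = 0.000162, adjusted p = 0.178 with an estimated correlation). Among them were PCO1 (AT5G15120, log2 6.97, SE 0.61, adjusted p = 7.77e-07), a plant cysteine oxidase, and LBD41 (AT3G02550, log2 4.89, SE 0.46, adjusted p = 1.84e-06). Of the abscisic acid and dehydration genes, 11 of 17 members were lower and 0 were higher (13 and 0 adjusted over the list alone, camera adjusted p = 1.48e-05, adjusted p = 0.178 with an estimated correlation). They included the dehydrins COR47 (AT1G20440, log2 -1.16, SE 0.21, adjusted p = 0.00068) and ERD10 (AT1G20450, log2 -1.59, SE 0.30, adjusted p = 0.001). In the heat shock list 11 of 22 members were higher and 0 were lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.409 with an estimated correlation).

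The largest rise at 0 h was in AT1G26420 (0 ± 0 CPM in Col-0 at 0 h and 1.44 ± 1.01 CPM in cat2 at 0 h). After CAT2, the largest falls were in KIN1 (AT5G15960, log2 -3.40 ± 0.76), COR15A (AT2G42540, log2 -3.30 ± 0.74) and HAI2 (AT1G07430, log2 -3.08 ± 0.66), all genes of the cold and abscisic acid response. In the vascular list 2 of 12 members were lower and 0 were higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.409 with an estimated correlation). These included the phloem sucrose carrier SUC2 (AT1G22710, log2 -0.60, SE 0.13, adjusted p = 0.00287). Altogether 4741 genes were called, 2349 higher and 2392 lower, and 936 and 287 differed at least 2-fold. The count depended on single libraries, as it was 2988 without Col-0 replicate 1, 2994 without Col-0 replicate 2 and 3048 without cat2 replicate 2. With library size as the only scaling, 83.1% of the called genes were higher, against 49.5%, and the median log2 of all genes was 0.115, against -0.03.

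The comparison of shr with Col-0 at 0 h asked what the lack of SHR changes in unstressed shoots. Phosphate starvation genes were higher throughout, as 13 of 13 members were higher and 0 were lower (camera adjusted p = 3.04e-16, adjusted p = 0.0147 with an estimated correlation). They included the phosphate transporter PHT1;4 (AT2G38940, log2 4.02, SE 0.18, adjusted p = 6.67e-12) and the glycerophosphodiesterase SRG3 (AT3G02040, log2 4.61, SE 0.24, adjusted p = 6.84e-11). In the anthocyanin list 17 of 20 members were higher and 2 were lower (camera adjusted p = 0.000391, adjusted p = 0.429 with an estimated correlation). They included CHS (log2 1.68, SE 0.25, adjusted p = 3.63e-05) and CHI (AT3G55120, log2 0.85, SE 0.14, adjusted p = 9.86e-05), while the repressor MYBL2 (AT1G71030, log2 -1.52, SE 0.16, adjusted p = 4.78e-07) was lower. In the salicylic acid list 15 of 25 members were higher and 0 were lower (camera adjusted p = 0.000734, adjusted p = 0.465 with an estimated correlation). Among them were the pathogenesis-related genes PR5 (AT1G75040, log2 3.22, SE 0.39, adjusted p = 3.75e-06) and PR2 (AT3G57260, log2 5.52, SE 0.89, adjusted p = 9.34e-05). Of the glutathione S-transferases, 19 of 24 members were higher and 0 were lower (camera adjusted p = 5.66e-06, adjusted p = 0.265 with an estimated correlation). Among them were GSTF6 (log2 4.90 ± 0.39) and GSTF7 (AT1G02920, log2 5.22 ± 0.49). Of the SHORT-ROOT regulon, 5 of 10 members were lower and 1 was higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0389, adjusted p = 0.429 with an estimated correlation). These included the direct target SCL23 (AT5G41920, log2 -1.29, SE 0.16, adjusted p = 2.86e-06) and the cyclin CYCD6;1 (AT4G03270, log2 -1.51, SE 0.19, adjusted p = 5.1e-06).

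Of the clock genes in shr at 0 h, 7 of 15 members were lower and 0 were higher (camera adjusted p = 0.00535, adjusted p = 0.15 with an estimated correlation). They included ELF3 (AT2G25930, log2 -0.58, SE 0.07, adjusted p = 1.67e-06) and GI (AT1G22770, log2 -0.48, SE 0.08, adjusted p = 0.000137). Clock genes of shr replicates 1 and 2 lay a median of 0.451 and 0.394 from the other libraries of the group. Among jasmonate genes, 14 of 24 members were higher and 0 were lower (15 and 0 adjusted over the list alone, camera adjusted p = 0.000648, adjusted p = 0.465 with an estimated correlation). These included AOC2 (log2 2.15 ± 0.30) and LOX2 (log2 2.29 ± 0.33). In the oxidative stress list 26 of 28 members were higher and 0 were lower (camera adjusted p = 5.66e-06, adjusted p = 0.462 with an estimated correlation). In both lists, and among glutathione S-transferases, replicate 1 of shr lay below the other shr libraries, by a median log2 of -0.95, -1.53 and -0.69. In the senescence list 9 of 18 members were higher and 0 were lower (camera adjusted p = 0.0389, adjusted p = 0.465 with an estimated correlation). They included SAG21 (AT4G02380, log2 3.19 ± 0.50) and WRKY53 (AT4G23810, log2 1.93 ± 0.35). Falls were largest in AT3G62950 (log2 -7.20, SE 0.56, adjusted p = 1.61e-08), AT5G35777 (log2 -5.29, SE 0.53, adjusted p = 4.07e-07) and AT1G47860 (log2 -4.43, SE 0.25, adjusted p = 9.8e-11). The largest rises were in NATA1 (AT2G39030, 0.0108 ± 0.0186 CPM in Col-0 at 0 h and 46.6 ± 56.6 CPM in shr at 0 h) and PHT3;2 (AT3G48850, 0 ± 0 CPM in Col-0 at 0 h and 7.98 ± 6.04 CPM in shr at 0 h). In total 9226 genes were called, 4326 higher and 4900 lower, and 1623 and 833 differed at least 2-fold. Scaled by library size only, 60.6% were higher, against 46.9%.

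The comparison of cat2shr with cat2 at 0 h asked what the lack of SHR changes in unstressed catalase mutants. Phosphate starvation genes were again higher throughout, as 13 of 13 members were higher and 0 were lower (camera adjusted p = 4.35e-18, adjusted p = 0.00896 with an estimated correlation). PHT1;4 (log2 3.94, SE 0.18, adjusted p = 1.3e-11) and PAP17 (AT3G17790, log2 4.72, SE 0.25, adjusted p = 1.72e-10), a purple acid phosphatase, were among them. Of the jasmonate genes, 17 of 24 members were lower and 1 was higher (18 and 1 adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.576 with an estimated correlation). Among them were JAZ2 (log2 -2.24, SE 0.29, adjusted p = 1.96e-05) and CYP94C1 (AT2G27690, log2 -3.59, SE 0.50, adjusted p = 2.84e-05), which turns over jasmonate. In the glucosinolate list 16 of 19 members were lower and 1 was higher (camera adjusted p = 8.32e-12, adjusted p = 0.0602 with an estimated correlation). These included the sulfotransferase SOT18 (AT1G74090, log2 -1.22, SE 0.11, adjusted p = 1.32e-07) and CYP79F2 (AT1G16400, log2 -3.06, SE 0.33, adjusted p = 1.66e-06). In the iron deficiency list 10 of 12 members were higher and 0 were lower (camera adjusted p = 3.73e-06, adjusted p = 0.513 with an estimated correlation). Among them were nicotianamine synthase NAS4 (AT1G56430, log2 1.86, SE 0.24, adjusted p = 1.17e-05) and the transporter OPT3 (AT4G16370, log2 1.03, SE 0.14, adjusted p = 2.13e-05).

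The largest rises in cat2shr at 0 h were in IPS1 (AT3G09922, 0 ± 0 CPM in cat2 at 0 h and 16.6 ± 4.08 CPM in cat2shr at 0 h), a non-coding RNA of phosphate starvation, and PAP14 (AT2G46880, 0.0107 ± 0.0185 CPM in cat2 at 0 h and 9.29 ± 4.85 CPM in cat2shr at 0 h). The next were AT1G23110 (log2 8.42, SE 0.44, adjusted p = 9.78e-11) and AT1G73010 (log2 7.32, SE 0.49, adjusted p = 7.17e-09). The largest falls were in AT3G62950 (log2 -5.16, SE 0.45, adjusted p = 1.11e-07), AT5G35777 (log2 -4.81, SE 0.57, adjusted p = 5.74e-06) and AT1G47860 (log2 -4.64, SE 0.25, adjusted p = 1.22e-10), the same 3 loci as in shr against Col-0. Of the 9226 and 7105 genes called for the lack of SHR in Col-0 and in cat2 at 0 h, 4864 had the same sign and 130 the opposite sign. Of the 7105 genes called here 3491 were higher and 3614 lower, and 811 and 889 differed at least 2-fold. A fit on only these 2 groups called 4712. 

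The comparison of cat2 with Col-0 at 24 h asked how far the catalase mutant differs from the wild type under stress. Heat shock genes were higher without exception, as 22 of 22 members were higher and 0 were lower (camera adjusted p = 1.66e-08, adjusted p = 0.564 with an estimated correlation). The heat shock factors HSFA8 (AT1G67970, log2 1.83, SE 0.12, adjusted p = 1.61e-10) and HSFA4A (log2 2.80, SE 0.19, adjusted p = 4.45e-10) were among them. Among low-oxygen genes, 11 of 13 members were higher and 0 were lower (camera adjusted p = 0.000174, adjusted p = 0.359 with an estimated correlation). They included PCO1 (log2 8.95, SE 0.60, adjusted p = 4.78e-10) and PDC1 (log2 7.43, SE 0.53, adjusted p = 1.24e-09). Of the oxidative stress markers, 26 of 28 members were higher and 0 were lower (27 and 0 adjusted over the list alone, camera adjusted p = 6.01e-07, adjusted p = 0.564 with an estimated correlation). These included UPOX (log2 5.55, SE 0.35, adjusted p = 2.62e-10) and SRO5 (log2 5.70, SE 0.53, adjusted p = 3.45e-08). In the photorespiration list 15 of 20 members were lower and 1 was higher (camera adjusted p = 0.000102, adjusted p = 0.564 with an estimated correlation). Among them were GS2 (log2 -1.28, SE 0.08, adjusted p = 7.66e-11) and the glutamate synthase GLU1 (AT5G04140, log2 -1.36, SE 0.11, adjusted p = 2.69e-09). In the salicylic acid list 17 of 25 members were higher and 0 were lower (camera adjusted p = 0.0156, adjusted p = 0.983 with an estimated correlation). These included the regulators SAG101 (log2 1.24, SE 0.11, adjusted p = 8.49e-09) and CBP60G (AT5G26920, log2 2.34, SE 0.32, adjusted p = 4.85e-06). In the vascular list 10 of 12 members were lower and 0 were higher (camera adjusted p = 0.0181, adjusted p = 0.665 with an estimated correlation). Among them was the cellulose synthase CESA4 (AT5G44030, log2 -0.76 ± 0.11) of secondary walls.

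The largest rises at 24 h were in the small heat shock protein gene HSP17.6C (AT1G53540, 0.0134 ± 0.0232 CPM in Col-0 at 24 h and 88 ± 27.8 CPM in cat2 at 24 h) and in GSTU25 (AT1G17180, log2 11.46, SE 1.13, adjusted p = 9.26e-08), a glutathione S-transferase. After CAT2, the largest falls were in BAM6 (AT2G32290, log2 -4.28, SE 0.35, adjusted p = 4.6e-09), a beta-amylase, AT2G36430 (log2 -3.19, SE 0.19, adjusted p = 3.63e-11) and FBA5 (AT4G26530, log2 -3.09, SE 0.32, adjusted p = 1.31e-07), a fructose-bisphosphate aldolase. Of the photosynthesis genes, 25 of 29 members were lower and 0 were higher (camera adjusted p = 3.24e-09, adjusted p = 0.564 with an estimated correlation). Altogether 13045 genes were called, 6385 higher and 6660 lower, and 2428 and 1697 differed at least 2-fold.

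The comparison of shr with Col-0 at 24 h asked what the lack of SHR changes under stress. Phosphate starvation genes stayed higher, as 13 of 13 members were higher and 0 were lower (camera adjusted p = 3.57e-12, adjusted p = 0.049 with an estimated correlation). PHT1;4 (log2 4.37, SE 0.19, adjusted p = 3.42e-12) and SQD1 (AT4G33030, log2 2.05, SE 0.10, adjusted p = 7.62e-12), of sulfolipid synthesis, were among them. In the iron deficiency list 12 of 12 members were higher and 0 were lower (camera adjusted p = 8.84e-06, adjusted p = 0.509 with an estimated correlation). Among them were OPT3 (log2 1.62, SE 0.14, adjusted p = 2.17e-08) and the peptide gene IMA1 (AT1G47400, log2 4.22, SE 0.42, adjusted p = 2.1e-07). In the cell cycle list 13 of 25 members were higher and 0 were lower (camera adjusted p = 7.39e-05, adjusted p = 0.722 with an estimated correlation). Among them were MCM2 (log2 2.03, SE 0.13, adjusted p = 4.84e-10) and MCM5 (log2 1.53, SE 0.11, adjusted p = 2.81e-09). Of the sugar starvation markers, 8 of 10 members were lower and 0 were higher (camera adjusted p = 9.78e-05, adjusted p = 0.509 with an estimated correlation). These included AKINBETA1 (log2 -2.32, SE 0.16, adjusted p = 9.77e-10) and SEN1 (AT4G35770, log2 -4.19, SE 0.43, adjusted p = 2.97e-07). Clock genes were lower, as 9 of 15 members were lower and 0 were higher (camera adjusted p = 0.00198, adjusted p = 0.0661 with an estimated correlation). These included TOC1 (AT5G61380, log2 -1.26, SE 0.10, adjusted p = 5e-09) and ELF3 (log2 -0.67, SE 0.07, adjusted p = 1.09e-07). In the salicylic acid list 14 of 25 members were higher and 1 was lower (15 and 1 adjusted over the list alone, camera adjusted p = 0.00621, adjusted p = 0.778 with an estimated correlation). They included PR5 (log2 3.03 ± 0.40) and PR2 (log2 4.66 ± 0.83).

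The largest rises at 24 h were in IPS1 (0 ± 0 CPM in Col-0 at 24 h and 36.4 ± 9 CPM in shr at 24 h) and PAP14 (0.0129 ± 0.0223 CPM in Col-0 at 24 h and 18 ± 3.38 CPM in shr at 24 h). The next were ATSDI1 (AT5G48850, log2 8.04, SE 0.41, adjusted p = 6.31e-11) and LSU1 (AT3G49580, log2 7.99, SE 0.31, adjusted p = 1.79e-12), both genes of sulfur deficiency. Falls were largest in AT1G19530 (log2 -6.92, SE 0.47, adjusted p = 1.58e-09), AT4G25580 (log2 -6.80, SE 0.62, adjusted p = 6e-08) and AT5G35777 (log2 -6.40, SE 0.45, adjusted p = 1.8e-09). Root markers were few in these shoots, and 2 of 5 members were lower and 1 was higher (camera adjusted p = 0.655). Among them CASP2 (AT3G11550, log2 -2.96, SE 0.60, adjusted p = 0.000356), a protein of the root endodermis, was lower. In total 10718 genes were called, 5252 higher and 5466 lower, and 1339 and 1199 differed at least 2-fold. Under library size scaling alone, 64.4% were higher, against 49%, and the median log2 of all genes was 0.135, against -0.002.

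The comparison of cat2shr with cat2 at 24 h asked what the lack of SHR changes in stressed catalase mutants. Heat shock genes were lower, as 21 of 22 members were lower and 0 were higher (camera adjusted p = 1.19e-10, adjusted p = 0.4 with an estimated correlation). HSFA8 (log2 -2.23, SE 0.12, adjusted p = 2.18e-11) and ROF2 (log2 -2.49, SE 0.20, adjusted p = 6.85e-09) were among them. Of the oxidative stress markers, 15 of 28 members were lower and 3 were higher (camera adjusted p = 0.038, adjusted p = 0.774 with an estimated correlation). They included UPOX (log2 -3.42, SE 0.31, adjusted p = 4.07e-08) and WRKY25 (log2 -2.19, SE 0.28, adjusted p = 3.81e-06). Of the low-oxygen genes, 8 of 13 members were lower and 1 was higher (camera adjusted p = 0.0288, adjusted p = 0.504 with an estimated correlation). Among them were PDC1 (log2 -3.12 ± 0.38) and LBD41 (log2 -2.33 ± 0.35). Of the abscisic acid genes, 11 of 17 members were higher and 1 was lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.00579, adjusted p = 0.504 with an estimated correlation). These included the proline synthesis gene P5CS1 (AT2G39800, log2 1.58, SE 0.15, adjusted p = 4.39e-08) and RD22 (AT5G25610, log2 1.84, SE 0.18, adjusted p = 8.71e-08). In the vascular list 8 of 12 members were higher and 1 was lower (camera adjusted p = 0.0288, adjusted p = 0.658 with an estimated correlation). Among them were the cellulose synthase CESA4 (log2 0.90 ± 0.11) and the xylan synthesis gene IRX9 (AT2G37090, log2 1.72 ± 0.24). Among cell cycle genes, 14 of 25 members were higher and 4 were lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.768 with an estimated correlation), with MCM7 (log2 1.37 ± 0.13) higher and CYCB1;1 (AT4G37490, log2 -3.23 ± 0.23) lower. In the phosphate list 13 of 13 members were higher and 0 were lower (camera adjusted p = 8.32e-11, adjusted p = 0.0771 with an estimated correlation).

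The largest rises in cat2shr at 24 h were in MGD3 (AT2G11810, log2 7.09, SE 0.45, adjusted p = 4.4e-10), of galactolipid synthesis, and AT1G23110 (log2 6.21, SE 0.38, adjusted p = 1.19e-10). The largest falls were in AT1G19530 (log2 -6.26, SE 0.37, adjusted p = 1.29e-10), HSP17.6C (log2 -6.12, SE 1.09, adjusted p = 0.000127) and HSP17.4 (AT3G46230, log2 -5.36, SE 1.1, adjusted p = 0.000488). Of the floral organ markers, 5 of 7 members were lower and 0 were higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.147). These included AP1 (log2 -3.44, SE 0.87, adjusted p = 0.00251) and PI (log2 -1.77, SE 0.45, adjusted p = 0.00264). Of the 10718 and 11204 genes called for the lack of SHR in Col-0 and in cat2 at 24 h, 6036 had the same sign and 885 the opposite sign. Altogether 11204 genes were called here, 5496 higher and 5708 lower, and 1304 and 1751 differed at least 2-fold.

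**Figure D4:**
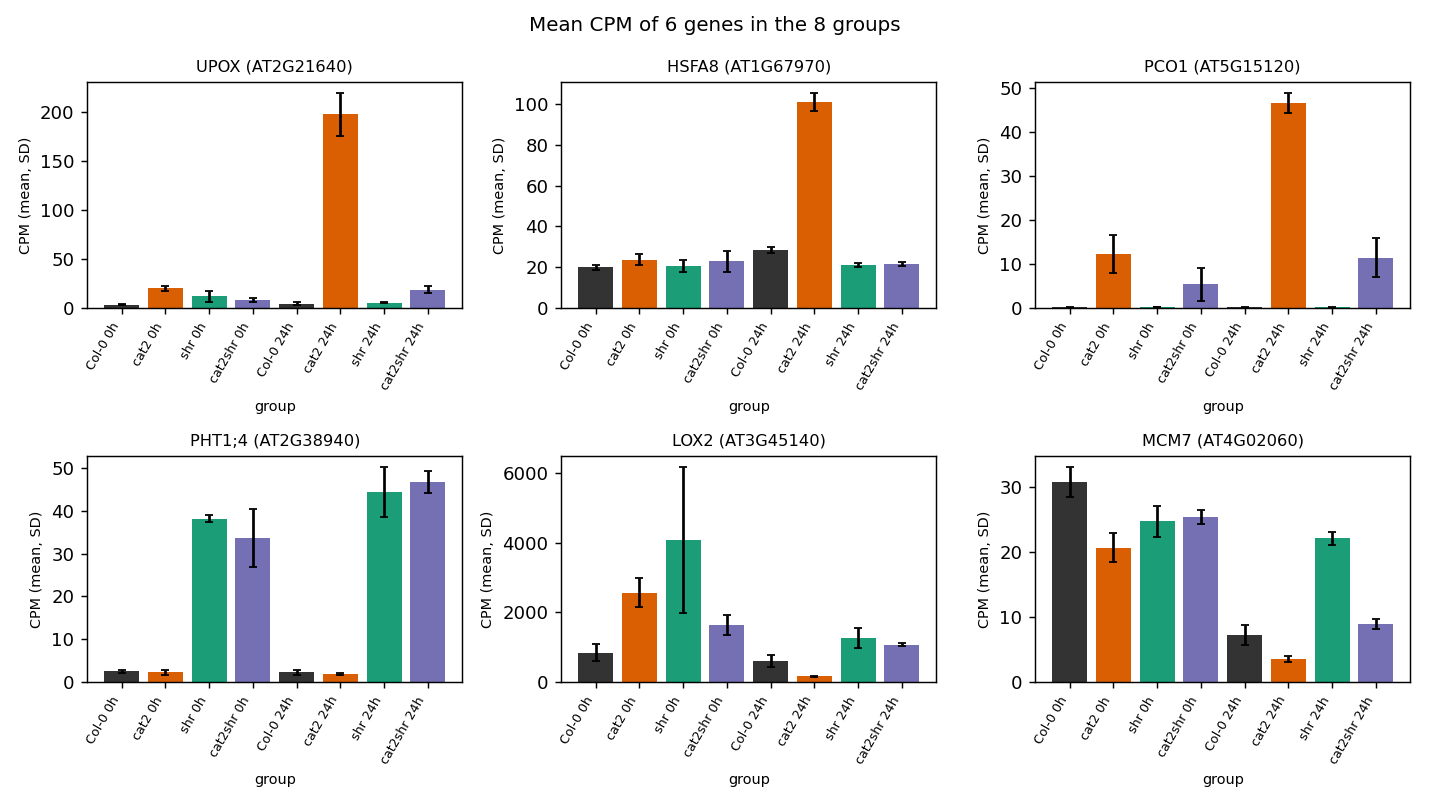
Mean CPM of 6 genes in the 8 groups (bars from 0, with SD over n = 3 libraries). UPOX, HSFA8 and PCO1 were highest in cat2 at 24 h, and PHT1;4 was high in shr and cat2shr at both times.

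The difference of stress responses between cat2 and Col-0 asked which responses depend on the catalase. Of the heat shock genes, 11 of 22 members were higher and 1 was lower (camera adjusted p = 0.000136, adjusted p = 0.844 with an estimated correlation). ROF2 (log2 2.98, SE 0.30, adjusted p = 3.5e-07) and HSFA8 (log2 1.58, SE 0.17, adjusted p = 7.43e-07) were among them. In the jasmonate list 12 of 24 members were lower and 0 were higher (14 and 0 adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.844 with an estimated correlation). Among them were LOX2 (log2 -3.52 ± 0.45) and AOC2 (log2 -2.84 ± 0.41). The list was higher in cat2 at 0 h and not called at 24 h. In the photorespiration list 12 of 20 members were lower and 0 were higher (13 and 0 adjusted over the list alone, camera adjusted p = 9.17e-05, adjusted p = 0.844 with an estimated correlation). They included GS2 (log2 -1.04, SE 0.11, adjusted p = 8.34e-07) and the glycolate oxidase GOX2 (AT3G14415, log2 -1.06, SE 0.14, adjusted p = 8.35e-06). In the low-oxygen list 6 of 13 members were higher and 0 were lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.844 with an estimated correlation). These included SUS1 (log2 3.16 ± 0.41) and ADH1 (log2 2.18 ± 0.55). The largest positive differences were in AT1G71000 (log2 8.12, SE 1.07, adjusted p = 1.23e-05), AT3G52115 (log2 5.90, SE 0.39, adjusted p = 1.48e-09) and AT3G41762 (log2 5.83, SE 1.1, adjusted p = 0.000426). After TAT3 (AT2G24850), the largest negative ones were in AT3G20340 (log2 -5.22, SE 0.65, adjusted p = 8.35e-06) and CML41 (AT3G50770, log2 -4.56, SE 0.79, adjusted p = 0.000187), a calmodulin-like gene. In total 7781 genes were called, 3825 with a higher and 3956 with a lower response in cat2. With library size as the only scaling, 32.3% were higher, against 49.2%, and the median log2 of all genes was -0.175, against -0.026.

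The difference of stress responses between shr and Col-0 was negative for 21 of 28 oxidative stress markers and positive for 0 (26 and 0 adjusted over the list alone, camera adjusted p = 1.24e-07, adjusted p = 0.477 with an estimated correlation). ERF6 (AT4G17490, log2 -3.48 ± 0.55) and WRKY33 (AT2G38470, log2 -3.69 ± 0.59) were among them. Of the glutathione S-transferases, 14 of 24 members were lower and 1 was higher (15 and 1 adjusted over the list alone, camera adjusted p = 0.000585, adjusted p = 0.477 with an estimated correlation). They included GSTF6 (log2 -4.78 ± 0.50) and GSTF2 (log2 -3.16 ± 0.46). In both lists shr replicate 1 at 0 h lay below its group, by a median log2 of -1.53 and -0.69. Of the oxidative stress markers, 26 of 28 were already higher in shr at 0 h. At 24 h 1 was higher and 8 lower (camera adjusted p = 0.655). In the cell cycle list 20 of 25 members were higher and 0 were lower (23 and 0 adjusted over the list alone, camera adjusted p = 6.65e-17, adjusted p = 0.208 with an estimated correlation). Among them were MCM2 (log2 2.17 ± 0.18) and MCM5 (log2 1.82 ± 0.16). At 0 h 16 of 25 were lower in shr, and at 24 h 13 were higher. Of the sugar starvation markers, 7 of 10 members were lower and 0 were higher (camera adjusted p = 0.000207, adjusted p = 0.477 with an estimated correlation). Among them were the glutamate dehydrogenase GDH2 (AT5G07440, log2 -3.38 ± 0.42) and AKINBETA1 (log2 -1.38 ± 0.22). The same library lay below by -0.93 in this list. The largest positive differences were in BHLH100 (log2 4.52, SE 0.72, adjusted p = 0.000294) and RD29A (AT5G52310, log2 3.44, SE 0.61, adjusted p = 0.000718), a dehydration marker. After NATA1, the largest negative one was in CYP710A1 (AT2G34500, log2 -9.96, SE 1.94, adjusted p = 0.00142), of sterol synthesis. Altogether 5235 genes were called, 2568 with a higher and 2667 with a lower response in shr.

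The difference of stress responses between cat2shr and cat2 asked where responses of the catalase mutant differ without SHR. Heat shock genes responded less in cat2shr, as 15 of 22 members were lower and 0 were higher (18 and 0 adjusted over the list alone, camera adjusted p = 2.62e-07, adjusted p = 0.573 with an estimated correlation). HSFA8 (log2 -2.19, SE 0.17, adjusted p = 3.43e-08) and ROF2 (log2 -2.63, SE 0.29, adjusted p = 2.38e-06) were among them. In the salicylic acid list 10 of 25 members were lower and 0 were higher (11 and 0 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.736 with an estimated correlation). They included SAG101 (log2 -1.65, SE 0.15, adjusted p = 2.86e-07) and CBP60G (log2 -3.17, SE 0.45, adjusted p = 4.99e-05). Among jasmonate genes, 12 of 24 members were higher and 1 was lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.702 with an estimated correlation). Among them were LOX2 (log2 3.41 ± 0.45) and AOC2 (log2 2.72 ± 0.41). The list was lower in cat2shr at 0 h and not called at 24 h. In the glucosinolate list 15 of 19 members were higher and 1 was lower (camera adjusted p = 7.8e-07, adjusted p = 0.306 with an estimated correlation). These included SOT18 (log2 1.83, SE 0.16, adjusted p = 1.36e-07) and SUR1 (AT2G20610, log2 1.75, SE 0.23, adjusted p = 2.32e-05). Of the antioxidant enzymes, 13 of 26 members were higher and 1 was lower (camera adjusted p = 0.000808, adjusted p = 0.302 with an estimated correlation). They included the superoxide dismutase FSD2 (AT5G51100, log2 0.99 ± 0.12) and the dehydroascorbate reductase DHAR3 (AT5G16710, log2 0.66 ± 0.11). The largest positive difference was in IMS2 (log2 5.26, SE 0.45, adjusted p = 1.49e-07) and the largest negative one in GAT1_2.1 (log2 -7.15, SE 0.69, adjusted p = 1.05e-06). In total 6288 genes were called, 3164 with a higher and 3124 with a lower response in cat2shr.

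The difference of stress responses between cat2shr and shr asked what the catalase mutation adds in shoots without SHR. Oxidative stress markers responded more in cat2shr, as 20 of 28 members were higher and 0 were lower (23 and 0 adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.5 with an estimated correlation). WRKY6 (log2 2.74, SE 0.47, adjusted p = 0.000346) and WRKY75 (AT5G13080, log2 5.71, SE 1.05, adjusted p = 0.000614) were among them. In this list shr replicate 1 at 0 h lay below its group by a median log2 of -1.53. Of the antioxidant enzymes, 10 of 26 members were higher and 4 were lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.5 with an estimated correlation). These included the glutathione synthesis gene GSH1 (AT4G23100, log2 1.06, SE 0.17, adjusted p = 0.000212) and the catalase CAT1 (AT1G20630, log2 1.15, SE 0.22, adjusted p = 0.00076). Among low-oxygen genes, 5 of 13 members were higher and 0 were lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.5 with an estimated correlation). They included SUS1 (log2 3.54, SE 0.40, adjusted p = 1.95e-05) and ADH1 (log2 2.33, SE 0.52, adjusted p = 0.00255). In the iron deficiency list 7 of 12 members were lower and 0 were higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.5 with an estimated correlation). Among them were IMA3 (log2 -1.54 ± 0.34) and BHLH100 (log2 -2.59 ± 0.61). The largest positive differences were in RHD2 (AT5G51060, log2 7.86, SE 1.3, adjusted p = 0.000279), an NADPH oxidase, and CYP710A1 (log2 7.73, SE 1.27, adjusted p = 0.000267). Altogether 7184 genes were called, 3559 with a higher and 3625 with a lower response in cat2shr. Scaled by library size only, 23.2% were higher, against 49.5%, and the median log2 of all genes was -0.242, against -0.008.

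The effect of the catalase mutation on the stress response was compared with and without SHR. Of the 7781 and 7184 genes called, 1645 were higher and 1929 lower in both, where independence gives 669.1 and 704.8, and 241 had opposite signs. Among the 2098 genes with at least a 2-fold difference with SHR, the median size was 1.43 with SHR and 0.58 without it. Among the 1986 genes chosen without SHR, it was 0.67 with SHR and 1.51 without it. Across all genes Pearson's r was 0.319 and Spearman's rho 0.439, and genes are not independent replicates.

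The three-way interaction asked where the catalase mutation changes the stress response by a different amount with and without SHR. Jasmonate genes were higher in this contrast, as 17 of 24 members were higher and 0 were lower (22 and 0 adjusted over the list alone, camera adjusted p = 9.35e-11, adjusted p = 0.366 with an estimated correlation). LOX2 (log2 4.58 ± 0.63) and AOC2 (log2 3.84 ± 0.57) were among them. Camera called the jasmonate list in all 3 genotype comparisons at 0 h, but in no comparison at 24 h (adjusted p from 0.813 to 0.984). In the photorespiration list 9 of 20 members were higher and 0 were lower (12 and 0 adjusted over the list alone, camera adjusted p = 1.17e-06, adjusted p = 0.366 with an estimated correlation). These included the lipoamide dehydrogenase mtLPD1 (AT1G48030, log2 1.09 ± 0.17) and GLU1 (log2 1.18 ± 0.22). Of the antioxidant enzymes, 7 of 26 members were higher and 0 were lower (10 and 0 adjusted over the list alone, camera adjusted p = 4.48e-05, adjusted p = 0.0958 with an estimated correlation). Among them were DHAR1 (AT1G19570, log2 2.93 ± 0.43) and APX1 (AT1G07890, log2 2.06 ± 0.37). In the heat shock list 5 of 22 members were lower and 1 was higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.0247, adjusted p = 0.607 with an estimated correlation). These included HSFA8 (log2 -1.70, SE 0.24, adjusted p = 0.000108) and ROF2 (log2 -2.60, SE 0.41, adjusted p = 0.000414). Replicate 1 of shr at 0 h lay below its group in the jasmonate and heat shock lists, by a median log2 of -0.95 and -1.40. The sucrose exporters SWEET12 (log2 2.54 ± 0.21) and SWEET11 (AT3G48740, log2 1.70 ± 0.24) were higher. The largest negative values were in AT3G52115 (log2 -6.53, SE 0.54, adjusted p = 4.35e-07), BRCA1 (AT4G21070, log2 -5.65, SE 0.53, adjusted p = 1.73e-06), of DNA repair, and TSO2 (AT3G27060, log2 -5.52, SE 0.41, adjusted p = 2.38e-07), a ribonucleotide reductase subunit. From 0 h to 24 h TSO2 went from 171 ± 37.7 to 881 ± 113 CPM in cat2, from 95.6 ± 4.61 to 18.4 ± 4.16 CPM in Col-0, from 143 ± 6.80 to 110 ± 11.8 CPM in shr and from 146 ± 31.4 to 65.9 ± 21.2 CPM in cat2shr. In total 2794 genes were called, 1391 higher and 1403 lower. Under library size scaling alone, 37% were higher, against 49.8%.

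**Figure D5:**
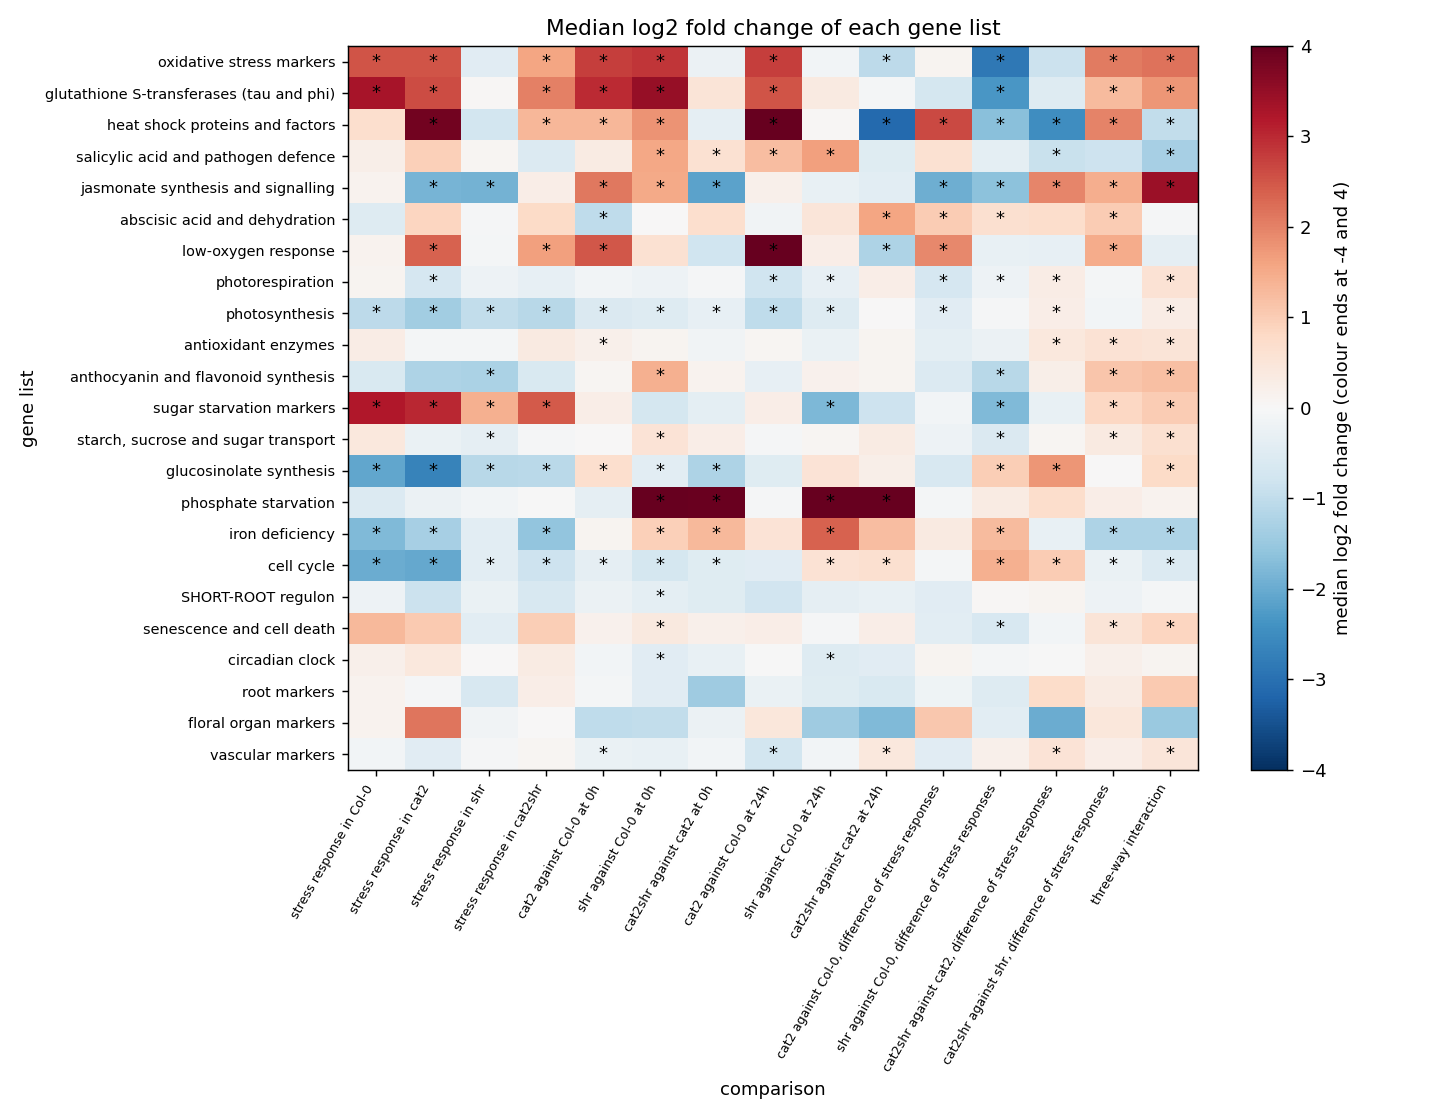
Median log2 fold change of the 23 gene lists (vertical axis) in the 15 contrasts (horizontal axis), with an asterisk where camera called the list at its preset correlation and members with 0 counts in a whole group set at their bound of 3 counts. Phosphate starvation genes stand out in the 4 comparisons of plants without SHR with plants that have it.

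Across the 15 contrasts, camera called between 6 and 16 lists at its preset correlation. With an estimated correlation it called 1 list, phosphate starvation, in shr at 0 h, in shr at 24 h and in cat2shr against cat2 at 0 h, and 0 lists in the other 12 contrasts. At an unadjusted p under 0.05 that setting called from 0 to 5 lists in a contrast.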

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

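The checks on replication genes and on SHR and CAT2 in 1 library, and the comparison of clock distances over all libraries, are tests chosen only after the result was seen. Differences of stress responses called 7781 genes for cat2 against Col-0 and 5235 for shr against Col-0. They called 6288 for cat2shr against cat2, 7184 for cat2shr against shr and 2794 in the three-way interaction. The counts of gene lists called in the same order were 6, 13, 9, 13 and 16.

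A first pattern is that stress responses differed between genotypes, and part may come from differences already present at 0 h. Most called genes would then differ more at 0 h than at 24 h. Of the called genes, 10.1% did so for cat2 against Col-0, 35.3% for shr against Col-0, 24.9% for cat2shr against cat2 and 7.2% for cat2shr against shr. These values argue against it as the main source in each of the 4 pairs, while it stays open for the genes behind each share. The genotypes themselves are the biological difference in the design, and growth or handling of each genotype was not varied apart from genotype.

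Other splits of the same libraries were counted for these differences, each in a fit on only the groups compared. For cat2 against Col-0, 3 of 40 splits gave as many genes as the real one, 7670 against a highest other of 9242. For shr against Col-0 it was 2 of 40, 5310 against 5557. For cat2shr against cat2 it was 4 of 40, 5250 against 10857, and for cat2shr against shr 5 of 40, 6389 against 8736. The other splits that called as many genes exchanged 0 or 3 libraries between the genotypes at 24 h and so left those groups whole. Such splits still hold the difference between genotypes at 24 h, so the count cannot decide on chance in these 4 cases. For the three-way interaction, 1 of 40 splits, the real one, gave as many genes, 2794 against a highest other of 1764. These splits redrew SHR status, so they also broke up the difference between plants with and without SHR. The count therefore cannot decide on chance in the interaction alone.

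In the 10 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes, and a share under 0.05 cannot be reached. The highest other split gave 0 genes in each. Real values were 11841 in Col-0, 14416 in cat2, 7160 in shr and 11820 in cat2shr for the stress response. At 0 h they were 5639 for cat2 against Col-0, 8275 for shr against Col-0 and 4712 for cat2shr against cat2. At 24 h they were 11871, 10341 and 10453 in that order.

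A second pattern is that genes of DNA damage and deoxynucleotide supply rose in cat2 under stress, such as TSO2 and BRCA1 in the three-way interaction. A candidate explanation is a DNA damage response, and in a further list of 18 such genes 15 rose in cat2, where 7876 of all 20347 genes rose. With an estimated correlation limma camera gave p = 0.0667 for the list in cat2 (5.19e-06 at the preset one, median log2 1.59) and p = 0.00976 for the difference between cat2 and Col-0 (15 of 18 higher, median log2 2.33), part of which was a fall of 8 of 18 in Col-0. More cells replicating DNA is argued against, since the replication genes had a median log2 change of -2.32 and 8 of 9 fell. The explanation by DNA damage was found and tested on the same data and no measure of DNA damage was used here.

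A further pattern is that shr replicate 1 at 0 h stood apart from the other shr libraries at 0 h, with lower oxidative stress, heat shock and jasmonate genes. A wrong label from a plant with an intact SHR gene is argued against by 1.02 CPM of SHR, where libraries with the intact gene held at least 4.41 CPM. A wrong label from cat2shr is argued against by 126 CPM of CAT2, where cat2 and cat2shr libraries held at most 32.5 CPM. Harvest at another time of day cannot be told apart, because its clock genes lay further from the other libraries than in 100% of 10000 random lists (0.451 against 0.119), but 12 of 24 libraries passed the 95th percentile of such lists. No biological explanation was tested for it.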

How the results depend on the processing

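The fits without shr replicate 1 and cat2shr replicate 1 at 0 h are tests chosen only after the result was seen. Over the alternatives, 394 values for the comparisons kept their direction and their side of the threshold, or stayed within 1.5 times the count, and 19 moved. Gene lists called by camera with an estimated correlation fell to 0 in 12 contrasts and to 1 in shr against Col-0 at 0 h and at 24 h and in cat2shr against cat2 at 0 h. The estimate inflates the variance of a list by the correlation of its members, which is part of that setting's construction. With the fit on only the groups compared, which uses fewer samples, cat2shr against cat2 at 0 h called 4712 genes.

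With 1 library left out at a time, cat2 against Col-0 at 0 h called 2988 to 4163 genes, and the cause of the low counts beyond fewer samples was not tested. The lowest were 2988 without Col-0 replicate 1, 2994 without Col-0 replicate 2 and 3048 without cat2 replicate 2. Called genes ranged from 10820 to 11531 for the stress response in Col-0, 14353 to 15142 in cat2, 6582 to 7683 in shr and 11936 to 12540 in cat2shr. Genotype differences ranged from 7507 to 8885 for shr against Col-0 and 5551 to 6577 for cat2shr against cat2 at 0 h. At 24 h they ranged from 11695 to 13188 for cat2 against Col-0, 9334 to 10127 for shr against Col-0 and 9927 to 10994 for cat2shr against cat2. Differences of stress responses ranged from 6645 to 8531 for cat2 against Col-0, 3975 to 5376 for shr against Col-0, 5120 to 7045 for cat2shr against cat2 and 5826 to 7603 for cat2shr against shr. The three-way interaction ranged from 2190 to 3143, and genes of the same sign in cat2 against Col-0 and cat2shr against shr from 3036 to 4135. CAT2 in cat2 ranged from log2 -4.56 to -4 at 0 h and -5.23 to -4.89 at 24 h. SHR in shr ranged from -3.23 to -3.14 and from -3.51 to -3.29, and in cat2shr against cat2 from -3.82 to -3.64 and from -3.61 to -3.41.

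Without both shr replicate 1 and cat2shr replicate 1 at 0 h, the stress response in shr called 7504 genes, 6934 of them shared with the 8404 of all libraries, and that in cat2shr 12339, with 11818 shared. Counts were 9215 for shr against Col-0 and 6835 for cat2shr against cat2 at 0 h, and 5270 for cat2 against Col-0 at 0 h. Among single named genes, 21987 values kept direction and side of the threshold, 127 passed it newly, 803 no longer passed it and 0 reversed. Replicate numbers were not taken as pairs, since in 26 of 84 pairs of the same number the correlation of residuals was over 0.1. Its median was 0.035, against -0.017 for other numbers, and 16 of 24 libraries had their highest mean correlation with their own number, so a weak shared effect stays open. With the replicate block the three-way interaction lost 1 list, glucosinolate synthesis, and 5 contrasts gained 1 or 2 lists. The effect of depth was not tested by subsampling.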

Other observations

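Genes of sulfur deficiency were higher in plants without SHR and in cat2, in a list written only after the main results were seen, as was the list of DNA damage genes below, and the members named here were chosen after their values were seen. Of 11 measured members, 10 were higher and 1 was lower in shr than in Col-0 at 24 h (median log2 3.42, camera p = 4.51e-08, p = 0.00822 with an estimated correlation). APR1 (AT4G04610), which reduces activated sulfate, was higher (log2 3.83, SE 0.24, adjusted p = 6.4e-10), as were the sulfate transporters SULTR1;2 (AT1G78000, log2 3.45, SE 0.21, adjusted p = 1.78e-10) and SULTR4;2 (AT3G12520, log2 3.33, SE 0.13, adjusted p = 5.73e-13). SULTR2;1 (AT5G10180) was lower (log2 -1.38, SE 0.17, adjusted p = 1.32e-06). At 0 h 10 of 11 members were higher in shr than in Col-0 (median log2 2.1, limma camera p = 2.82e-09, p = 0.00464 with an estimated correlation). In cat2shr against cat2 at 0 h it was also 10 of 11 (median log2 1.31, limma camera p = 5.95e-08, p = 0.00857 with an estimated correlation). In cat2 against Col-0 at 0 h 9 of 11 were higher (median log2 1.05, limma camera p = 1.06e-07, p = 0.00944 with an estimated correlation). The list was also higher in cat2 than in Col-0 at 24 h (10 of 11 higher, median log2 2.91, camera p = 1.26e-05, p = 0.0266 with an estimated correlation). Under stress it went in opposite directions in Col-0, where 7 of 11 fell (median log2 -1.36, camera p = 0.0116, p = 0.18 with an estimated correlation), and in cat2shr, where 10 of 11 rose (median log2 1.49, camera p = 4.69e-05, p = 0.0391 with an estimated correlation). In cat2 7 of 11 rose and 2 fell (median log2 0.94, limma camera p = 0.208, p = 0.496 with an estimated correlation). In shr 1 of 11 fell, with a median log2 of -0.04.

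Of 18 DNA damage genes, 15 rose and 1 fell under stress in cat2 (median log2 1.59, limma camera p = 5.19e-06, p = 0.0667 with an estimated correlation). In Col-0 8 of 18 fell and 0 rose (median log2 -0.53, limma camera p = 0.0216, p = 0.337 with an estimated correlation). At 0 h 11 of 18 were already higher and 2 lower in cat2 than in Col-0 (median log2 0.84, limma camera p = 1.29e-07, p = 0.0375 with an estimated correlation). TK1a (AT3G07800), a thymidine kinase, rose in cat2 (log2 2.95, SE 0.15, adjusted p = 2.75e-12). PARP1 (AT2G31320), a poly(ADP-ribose) polymerase, rose too (log2 1.51, SE 0.13, adjusted p = 1.62e-09), while RNR1 (AT2G21790) fell (log2 -0.85, SE 0.12, adjusted p = 2.36e-06). Of 18 members, 2 rose and 6 fell in cat2shr. The difference between the responses of cat2shr and cat2 was negative for TK1a (log2 -2.96, SE 0.20, adjusted p = 1.19e-08). Over the list 13 of 18 members were lower in this difference and 0 were higher (median log2 -1.87, limma camera p = 2.25e-12, p = 0.00828 with an estimated correlation).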
